A study of Mus musculus with 13 samples.

How the data were processed

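RNA from the abdominal aorta of 10-month-old C57BL/6 mice was sequenced in 13 libraries. Per the labels, the tissue was frozen on dry ice, RNA was extracted with Trizol, and libraries were built with a TruSeq RNA kit from 1 ug of total RNA. The deposited table gives FPKM made by the authors (fragments per kilobase of gene, scaled to the mapped fragments of the library) for 54532 gene identifiers in 13 columns, 1 per library. The labels name Bowtie 0.12.2 and the genome builds mm8 and mm9 without saying what each was used for. The identifiers are Ensembl mouse genes, and 54409 of them were found in the GENCODE M21 annotation, which was made on a later build. The program that counted fragments, its annotation, its treatment of fragments that match several places and any filter are not stated. No counts were available, so count-based tools were not run, and the number of fragments behind a value is unknown. No counting interval or lower limit of detection is given for that reason.

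Symbols were taken from GENCODE M21 by identifier, and 123 identifiers without a symbol kept their identifier. The FPKM sum per library lay between 630862 and 972283. Relative depth was estimated from the spacing of FPKM values under 0.5 shared by pairs of libraries. The estimated depths spanned 2.33-fold, and 70 of 78 pairs fitted 1 common scale within 0.03 on the natural log scale. The lowest estimate was in the library labelled knockout replicate 2, which had the most genes above 0. It had 39922, against 20493 to 33206 in the other libraries. The estimate thus did not follow the number of genes above 0, and the cause was not tested. Absolute depth cannot be had from these values.

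A gene was tested if it reached 1 FPKM in at least 3 libraries, which left 14850 genes. Values were analysed as log2(FPKM + 1), with no further scaling between libraries. A linear model with 1 mean per group was fitted to all 13 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean. The 3 groups share 1 estimate of spread, because the smallest has 3 libraries. All 3 pairs of groups were compared, p-values were adjusted by the Benjamini-Hochberg method within a comparison, and the threshold was an adjusted p of 0.05. Standard errors (SE) are those of limma, and p-values measure the spread between these libraries. The labels do not say whether each library came from a different mouse. Fold changes are differences of means on the log2(FPKM + 1) scale, so they are smaller than ratios of FPKM for genes at low levels.

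Selplg was compared between groups by exact two-sided permutation tests. A set of 27 gene lists with 537 symbols was tested with camera from limma, with a preset correlation of 0.01 between genes and adjustment over the lists within a comparison. Each list needed at least 3 measured members. The lists were also tested with a correlation estimated from the data and with fry, which asks whether the members of a list move 1 way on balance. Changed members were counted after adjustment over all genes and after adjustment over the list alone.

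The rule for named genes took Selplg first. It then took up to 10 rising and up to 10 falling genes with the largest fold changes among genes past the threshold. These had to have a mean of at least 2 FPKM in the higher group and no overlap between the libraries of both groups, and unnamed gene models were left out. It then took up to 4 changed members of each list. For a list without a changed member it took up to 2 members with a mean of at least 2 FPKM, given as values. Gene positions came from GENCODE M21, and genes within 10 Mb of Selplg were compared with all others by a two-sided Fisher's exact test. The groups, comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined.

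The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, a fit of both compared groups alone, no mean-variance trend, array weights, a term for replicate number, a minimum change of 2-fold, windows of 5 and 20 Mb around Selplg, and each library left out in turn. Rescaling used the FPKM sum without 54 genes, namely mitochondrial, haemoglobin and ribosomal-RNA-like genes and unnamed gene models of very high mean level. Those models ranged from 2484 FPKM in Gm26377 to 31711 FPKM in Gm28661. This rescaling was added after the data were examined. So were some alternatives for the count of opposite changes, namely this rescaling, the replicate term, array weights, no trend, the 2-fold minimum and each library left out. Other splits of the libraries were also tested.

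The gene test was tried on simulated data built from 14850 genes, with the spread of each gene in these libraries. The noise was drawn independently for each gene, with 1 spread for all groups. Correlation between genes, unequal spread of groups and outlying libraries were not simulated, so the shares and false calls below need not hold for these data. For treated against untreated wild type it recovered 12% of genes simulated at a log2 change of 1, 58% at 2, 96% at 4 and 100% at 6, with 10 false calls among 143. For the libraries labelled knockout against treated wild type the shares were 12%, 68%, 96% and 98%, with 3 false calls among 140. For the libraries labelled knockout against untreated wild type they were 12%, 82%, 98% and 100%, with 5 false calls among 151. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.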

Results

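RNA levels were measured in the abdominal aorta in 3 groups of libraries. They came from untreated wild-type mice (n = 5), wild-type mice given DOCA plus salt (treated wild type, n = 3), and mice labelled PSGL-1 knockout that were given the same treatment (labelled knockout, n = 5). DOCA is deoxycorticosterone acetate, a mineralocorticoid hormone. PSGL-1, encoded by Selplg, is a ligand on leukocytes for the selectins of the vessel wall. The title of the series speaks of AAA samples, and the labels do not say which of the aortas had a lesion. There was no untreated knockout group, so the effect of the treatment in knockout mice, and its difference from that in wild type, could not be tested.

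Between 10219 and 14059 genes reached 1 FPKM per library, and the lowest number was in labelled knockout replicate 3. Mitochondrial genes held 43.7% ± 6.45 (SD, n = 5) of the FPKM sum in untreated wild type. Their share was 21.7% ± 9.53 (SD, n = 3) in treated wild type and 38.4% ± 14.2 (SD, n = 5) in the libraries labelled knockout. Haemoglobin genes held 31.6% of the FPKM sum in treated wild-type replicate 3 and at most 2.31% in the other libraries. Ribosomal-RNA-like genes held 35.0% in treated wild-type replicate 2 and at most 11.1% in the other libraries. These shares leave out the unnamed models of very high level. Without all 54 genes left out in rescaling, between 15.2% (labelled knockout replicate 3) and 57.3% (labelled knockout replicate 4) of the FPKM sum remained. The first principal component held 35.5% of the variance. Labelled knockout replicate 4 lay at 70.4 on it, beside the treated wild-type libraries (72.0 to 79.5) and apart from the other libraries labelled knockout (-35.3 to -18.3).

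**Figure D1:**
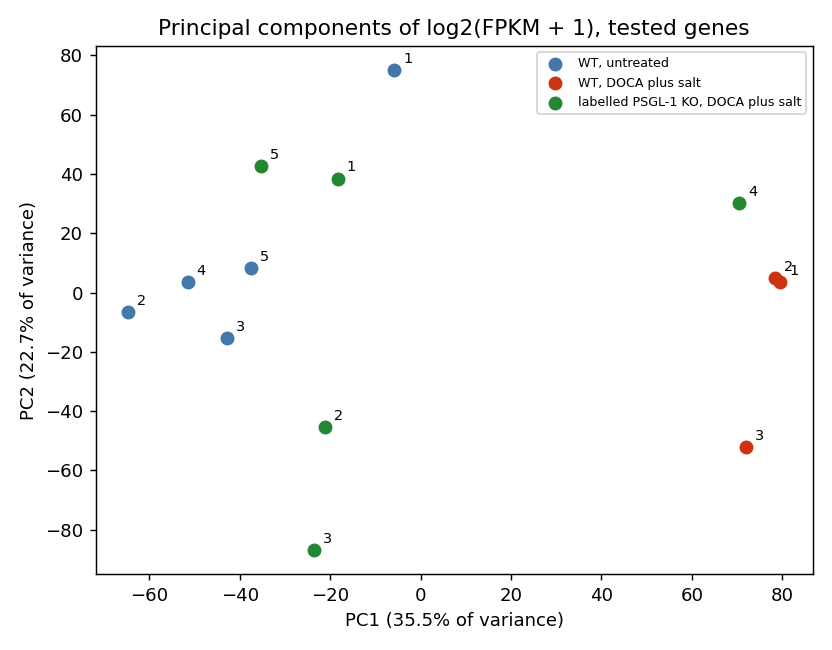
Each point is 1 library, placed by its first and second principal components of log2(FPKM + 1) over 14850 genes, coloured by group and marked with its replicate number. Labelled knockout replicate 4 sits at 70.4 on the first component, next to the 3 treated wild-type libraries at 72.0 to 79.5.

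Selplg, the gene named in the knockout, was compared first. Selplg (ENSMUSG00000048163) lies on chromosome 5 from 113818536 to 113832644 on the minus strand in GENCODE M21, and no other annotated gene overlaps it. Selplg RNA was present in each of the 5 libraries labelled knockout, at 1.52, 0.392, 2.55, 0.832 and 7.62 FPKM in replicates 1 to 5. Untreated wild type held 2.04, 1.90, 3.22, 2.99 and 3.54 FPKM, with a mean of 2.74 ± 0.728 (SD, n = 5). Treated wild type held 16.8, 1.65 and 27.3 FPKM, with a mean of 15.3 ± 12.9 (SD, n = 3). Its replicates 1 and 3, with the higher Selplg levels, also held the higher platelet and erythrocyte list means (9.06 and 10.2, against 4.29 in replicate 2) and neutrophil list means (4.84 and 5.45, against 1.65). The mean of the leukocyte genes named further below differed less, at 5.35, 4.58 and 4.86 (log2) in replicates 1 to 3. The libraries labelled knockout had a mean Selplg level of 2.58 ± 2.93 FPKM (SD, n = 5). Values per gene cannot show whether an RNA is intact or disrupted. The libraries labelled knockout were not separated from wild type by Selplg level.

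The difference in Selplg was 1.58 (log2) between treated and untreated wild type, with an exact permutation p of 0.107. It was -1.94 between the libraries labelled knockout and treated wild type (exact p = 0.0893) and -0.36 between the libraries labelled knockout and untreated wild type (exact p = 0.484). The smallest p that the design allows is 0.0179 for 3 against 5 libraries and 0.00794 for 5 against 5. Without treated wild-type replicate 2 the first difference was 2.61 and the second -2.97, and without labelled knockout replicate 5 the last was -0.75, each with an exact p of 0.0476. For 2 against 5 libraries, as in the first and second of these, this is the smallest p possible. The gene test gave no call for Selplg in any comparison (adjusted p = 0.118, 0.138 and 0.997). Among tested genes within 10 Mb of Selplg, 1 of 234 changed between the libraries labelled knockout and treated wild type, against 159 of 14598 elsewhere (Fisher's exact test, p = 0.524). None of those 234 genes had all 5 libraries labelled knockout above or below all 8 wild-type libraries.

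**Figure D2:**
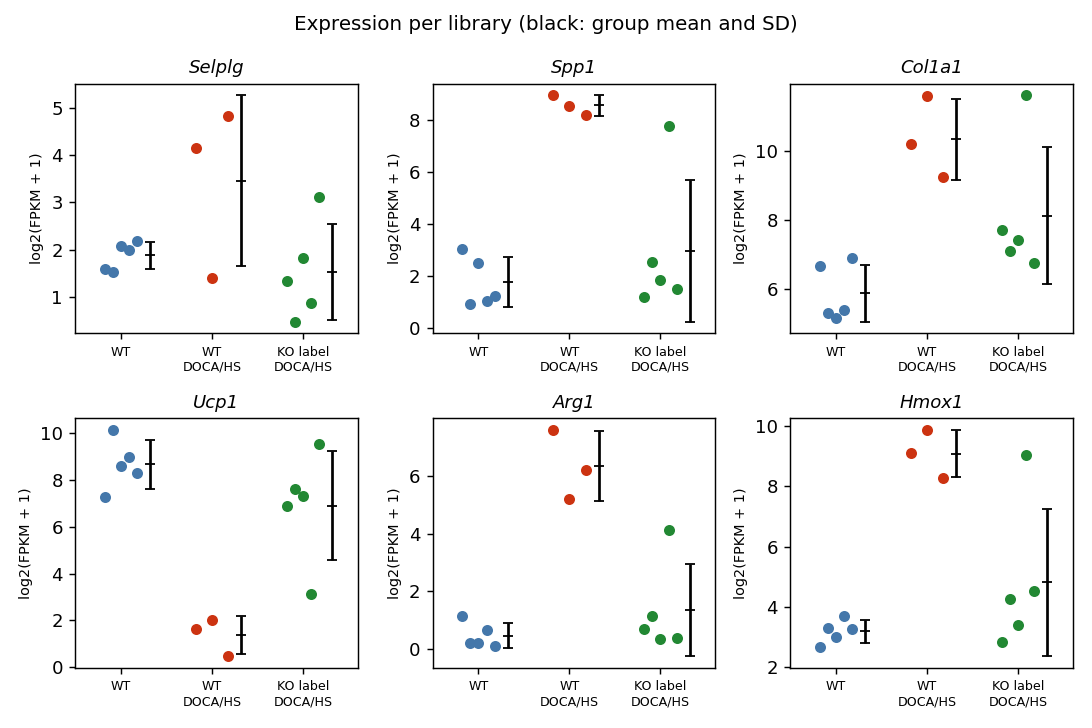
Each point is 1 library, the vertical axes show log2(FPKM + 1) for 6 genes, and black bars show the group mean and SD. In Spp1, Col1a1, Arg1 and Hmox1 labelled knockout replicate 4 is the highest of its group, at 218, 3130, 16.6 and 523 FPKM.

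The first comparison, treated against untreated wild type, asks what DOCA plus salt did to the RNA of the aorta. Lists of macrophage, chemokine, cell cycle and matrix genes were called higher after treatment by camera, and lists of fat cell genes lower. None of these calls held with an estimated correlation (adjusted p between 0.310 and 0.413). That correlation was 0.315 to 0.852 in these lists, far above the preset 0.01. With fry all but the matrix call held (adjusted p up to 0.0142, and 0.0797 for matrix). Spp1, which encodes osteopontin, rose from 3.07 ± 2.83 (SD, n = 5) to 385 ± 104 FPKM (SD, n = 3). Ucp1, the uncoupling protein of brown fat, fell from 495 ± 371 (SD, n = 5) to 1.84 ± 1.34 FPKM (SD, n = 3). In all, 2003 of 14850 genes changed by limma, 1212 upward and 791 downward, and 1940 of them by at least 2-fold. The libraries of both groups did not overlap in 4261 genes (28.7%), where chance gives 3.57%.

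The 9 other genes with the largest rise by the naming rule were Cxcl2, Hmox1, Arg1, Junb, Il1b, Cthrc1, Clec4n, Thbs1 and Ccl7. Cxcl2, which attracts neutrophils, rose by 6.66 (log2, SE 0.91) to 140 ± 115 FPKM (SD, n = 3). Hmox1, encoding a haem oxygenase, rose by 5.91 (SE 0.96), and Arg1, encoding an arginase of alternatively activated macrophages, by 5.87 (SE 0.72). Il1b, an inflammatory cytokine, rose by 5.30 (SE 0.80), and Ccl7, a monocyte attractant, by 4.94 (SE 0.80). Cthrc1, a product of activated fibroblasts, rose by 5.07 (SE 0.88), the lectin gene Clec4n by 4.97 (SE 0.92) and Thbs1, encoding a thrombospondin, by 4.95 (SE 1.03). Their adjusted p-values lay between 0.00207 and 0.00616. Junb was listed at 0 in 3 untreated libraries and 4 libraries labelled knockout, with 29.3 and 11.9 FPKM in the other untreated ones and 172, 126 and 188 FPKM in treated wild type. No fold is given for it, because the cause of these zeros is unknown. Of 3912 genes with a median of at least 10 FPKM, 8 were also listed at 0 in 1 to 3 libraries. Junb, at 0 in most libraries, is not among them. Some of their zeros may be true low values, as in Cpt1b (0.0573, 0.249 and 0 FPKM in treated wild type).

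Macrophage, chemokine and neutrophil lists were called upward, and the T and NK cell, B and plasma cell, mast cell, interferon and selectin lists were not. In the monocyte and macrophage list 12 of 22 members rose and 2 fell (18 and 3 adjusted over the list alone). The camera test gave an adjusted p of 3.66e-08, and adjusted p = 0.389 with an estimated correlation. Trem2, a receptor of lipid-handling macrophages, rose by 4.31 (log2, SE 0.57), Lgals3 by 3.31, the lysozyme gene Lyz2 by 3.05 and Cd68 by 3.01. Among chemokines and cytokines 18 of 36 rose and 3 fell (23 and 3 adjusted over the list alone; camera adjusted p = 9.25e-09, and adjusted p = 0.389 with an estimated correlation). Retnla, a product of alternatively activated macrophages, fell by 5.03 on the log2 scale. In the neutrophil list 4 of 9 rose (6 adjusted over the list alone; camera adjusted p = 4.82e-05, and adjusted p = 0.389 with an estimated correlation). They were Clec4d, up 4.12, the decoy receptor gene Il1r2, up 3.13, Csf3r, up 2.90, and Trem1, which was listed at 0 in all 5 untreated libraries and at 4.22 ± 3.15 FPKM (SD, n = 3) in treated wild type.

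Cell cycle genes rose in 19 of 20 members (20 adjusted over the list alone; camera adjusted p = 2.69e-18, and adjusted p = 0.310 with an estimated correlation). Birc5 rose by 4.54 (log2, SE 0.66), Ccnb2 by 3.51, Top2a by 3.17 and Ccna2 by 3.15. Among extracellular matrix genes 12 of 29 rose and 1 fell (14 and 2 adjusted over the list alone; camera adjusted p = 6.54e-06, and adjusted p = 0.413 with an estimated correlation). The collagen genes Col1a1 and Col8a1 rose by 4.44 (SE 0.88) and 4.41 (SE 0.96). Among proteases and their inhibitors 9 of 27 rose and 2 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.00200, and adjusted p = 0.501 with an estimated correlation). Timp1, an inhibitor of metalloproteinases, rose by 4.34, Adam8 by 3.96 and the membrane metalloproteinase gene Mmp14 by 3.81, and Timp4 fell by 4.20.

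Among platelet and erythrocyte genes 8 of 10 rose (10 adjusted over the list alone; camera adjusted p = 3.58e-06, and adjusted p = 0.389 with an estimated correlation). The list mean was 9.06 and 10.2 (log2) in treated wild-type replicates 1 and 3 and 4.29 in replicate 2, against 3.16 to 5.02 in untreated wild type. The neutrophil list followed the same libraries, with 4.84, 5.45 and 1.65 in replicates 1, 3 and 2, against 0.542 to 2.48 in untreated wild type. Replicate 2 thus lay within the untreated range of that list. Of its 9 members, 1 reached 1 FPKM in every untreated library. Ppbp, a platelet chemokine gene, rose by 3.69 (SE 0.84) and the erythroid enzyme gene Alas2 by 4.09 (SE 1.16). The Ppbp call was lost without treated wild-type replicates 1 (adjusted p = 0.0678) and 3 (0.0511) and with no filter. The Alas2 call was lost without the same libraries (0.0803 and 0.146) and untreated replicate 3 (0.0533), with no filter and with both groups fitted alone. Hba-a1 and Hba-a2 differed by 4.23 and 3.95 (adjusted p = 0.0457 and 0.0465). Both calls were lost with no filter, median-of-ratios scaling, quantile normalization, both groups fitted alone, the replicate term and rescaling. They were also lost without any 1 of untreated replicates 1 to 5, treated wild-type replicates 1 and 3 and labelled knockout replicates 2, 3 and 5 (adjusted p from 0.0511 to 0.287). Without treated wild-type replicate 2 the mean difference of the list went from 3.49 to 5.26. Among immediate early genes 5 of 22 rose, Fos by 3.74, Socs3 by 3.53 and Fosb by 3.42 among them (6 adjusted over the list alone; camera adjusted p = 1.08e-05, and adjusted p = 0.405 with an estimated correlation). The Fos and Fosb calls were lost with no filter and without treated wild-type replicate 2 (adjusted p = 0.0788 and 0.0917). The Fos call was also lost without treated wild-type replicates 1 (0.0631) and 3 (0.0588) and untreated replicate 2 (0.0540).

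Fat cell genes fell. All 17 measured white adipocyte markers were lower (17 adjusted over the list alone; camera adjusted p = 5.5e-18, and adjusted p = 0.310 with an estimated correlation). The log2 change was -5.46 in Gpd1, which makes glycerol phosphate for fat synthesis, -4.96 in Pck1, -4.83 in the lipid droplet gene Plin1 and -4.64 in Cfd, which encodes adipsin. Among brown adipocyte markers 9 of 10 fell (10 adjusted over the list alone; camera adjusted p = 3.93e-11, and adjusted p = 0.310 with an estimated correlation). The change was -7.28 in Ucp1, -7.05 in Cidea, -6.71 in Cox8b and -4.44 in Cox7a1. Other large falls by the naming rule were -5.77 in Cpt1b, which brings fatty acids into mitochondria, -5.64 in Inmt, -5.62 in Aspg, -5.42 in Thrsp, -5.23 in Ces1d and -5.14 in Adig.

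Genes of oxidative phosphorylation fell in 9 of 22 members (16 adjusted over the list alone; camera adjusted p = 1.41e-09, and adjusted p = 0.389 with an estimated correlation), and Cyc1 fell by 2.12 and Ndufv1 by 2.08. Both gene calls were lost with no filter and without each of treated wild-type replicates 1 (adjusted p = 0.0714 and 0.0560), 2 (0.0812 and 0.0624) and 3 (0.109 and 0.0726). The Cyc1 call was also lost with the replicate term and without untreated replicates 2 (0.0744) and 4 (0.0634). Endothelial markers fell in 5 of 19 (6 adjusted over the list alone; camera adjusted p = 1.08e-05, and adjusted p = 0.413 with an estimated correlation). The water channel gene Aqp1 fell by 3.24, Sox17 by 2.20, and the growth factor receptor genes Kdr and Flt1 by 2.14 and 2.01. The Sox17, Kdr and Flt1 calls were lost with no filter and without treated wild-type replicates 2 (adjusted p = 0.103, 0.0656 and 0.0592) and 3 (0.0731, 0.0921 and 0.0553). Without untreated replicate 2 the Sox17 and Kdr calls were lost (0.0548 and 0.0530), Sox17 also without untreated replicate 5 (0.0530), and Kdr also with the replicate term. Among genes that respond to mineralocorticoids and glucocorticoids 6 of 19 fell and none rose (6 adjusted over the list alone; camera adjusted p = 0.000393, and adjusted p = 0.389 with an estimated correlation). Pdk4 fell by 4.41, Orm1 by 4.26, Zbtb16 by 3.48 and Hsd11b1, encoding an enzyme that reactivates glucocorticoids, by 2.97. Among circadian clock genes 6 of 19 fell and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.00256, and adjusted p = 0.413 with an estimated correlation). The clock output gene Dbp fell by 2.45 and the repressor gene Nr1d1 by 2.51. It was not tested whether a lower share of fat, weighed below for adipocyte markers, also lowers the lists named here.

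Fibroblast markers moved both ways, with 5 of 20 lower and 2 higher (7 and 3 adjusted over the list alone; camera adjusted p = 0.0324, and adjusted p = 0.507 with an estimated correlation). The change was -4.15 in Clec3b, -3.14 in Scara5 and -2.98 in Gsn, while Cthrc1 rose. Nerve and Schwann cell markers fell in 2 of 12, S100b by 1.94 and Gfra3 by 1.34 (2 adjusted over the list alone; camera adjusted p = 0.00698, and adjusted p = 0.501 with an estimated correlation). Renin-angiotensin genes fell in 2 of 8, Ace by 1.75 and Mme by 1.40 (2 adjusted over the list alone; camera adjusted p = 0.0363, and adjusted p = 0.389 with an estimated correlation). Striated muscle genes were called upward as a list without a changed member (camera adjusted p = 0.00256, and adjusted p = 0.507 with an estimated correlation). Their list mean was 4.68 in treated wild-type replicate 3, 2.53 in replicate 1 and 0.90 in replicate 2, and the call was lost without replicate 3 (adjusted p = 0.338). The fibroblast call was lost without untreated replicate 3 (adjusted p = 0.0731), treated wild-type replicates 1 (0.0503) and 3 (0.0857) and labelled knockout replicate 4 (0.0679), and under median-of-ratios scaling, both groups fitted alone, the replicate term and rescaling. The nerve and renin-angiotensin calls were lost without untreated replicate 1 (adjusted p = 0.155 and 0.0532) and treated wild-type replicate 2 (0.0717 and 0.0821), and both under array weights and rescaling. The renin-angiotensin call was also lost under the filter at 5 FPKM, median-of-ratios scaling, quantile normalization and both groups fitted alone. Without untreated replicate 1 the mean difference of the nerve list went from -0.87 to -0.13 (log2), and it was -1.61, -0.55 and -0.45 without treated wild-type replicates 1, 2 and 3. For fibroblast markers it went from -0.48 to -0.81 and -0.13 without treated wild-type replicates 2 and 3, and for striated muscle genes from 1.86 to 0.87 without replicate 3. The Gfra3, Ace and Mme gene calls were lost with no filter and without treated wild-type replicates 1 (adjusted p = 0.0529, 0.0746 and 0.0815) and 3 (0.0977, 0.116 and 0.0998). Without treated wild-type replicate 2 and untreated replicate 2 the Gfra3 (0.0863 and 0.0553) and Mme (0.0935 and 0.0763) calls were lost, and Mme also without untreated replicates 3 (0.0606) and 4 (0.0712) and with the replicate term.

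The other 9 lists gave no call. Smooth muscle contractile genes held 0 changed of 22 members (camera adjusted p = 0.154), with Myh11 at 91.6 ± 90.8 FPKM (SD, n = 5) in untreated and 7.95 ± 4.50 FPKM (SD, n = 3) in treated wild type (adjusted p = 0.123). In the selectin and leukocyte adhesion list 3 of 18 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0609). Itgb2, Itgam and Cd44 rose by 2.39, 1.85 and 1.79, and Jam2 fell by 2.63. The Itgam call was lost with no filter and without treated wild-type replicates 1 (adjusted p = 0.113) and 3 (0.0692) and untreated replicate 5 (0.0584), and the Cd44 call without treated wild-type replicate 1 (0.0615). Among interferon responsive genes 2 of 20 rose, Isg15 and Oas1a, and 2 fell, Ifi27l2a and Gbp2 (3 and 2 adjusted over the list alone; camera adjusted p = 0.566). All 4 of these gene calls were lost with no filter and without treated wild-type replicate 3 (adjusted p = 0.0771 to 0.149). Oas1a was also lost with pseudocounts of 0.1 and 0.5, the filter at 5 FPKM and rescaling, without untreated replicates 1 to 5 and treated wild-type replicate 1 and without labelled knockout replicate 2 (0.0502 to 0.191). Gbp2 was also lost with the replicate term, without untreated replicates 2 to 5, treated wild-type replicates 1 and 2 and labelled knockout replicates 1 and 2 (0.0507 to 0.160). Isg15 was also lost after rescaling and without untreated replicates 2, 4 and 5 and treated wild-type replicates 1 and 2 (0.0555 to 0.0731), and Ifi27l2a without treated wild-type replicate 2 (0.0615). No member changed among mast cell markers (7 measured), T and NK cell markers (7), B and plasma cell markers (4), kidney and adrenal cortex markers (3), unfolded protein response genes (17) and sex-linked genes (4), also when adjusted over the list alone, with camera adjusted p between 0.149 and 0.934. The T and NK list had a median of 0.03 and a downward test, and the B and plasma list a median of 0.05 and a mean of -0.05.

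The naming rule picked 81 gene calls in this comparison, and Bhlhe40, Per3, Ndufa4 and Ndufs1 among them are not named above. Of the 81, 18, 14 and 22 were lost without treated wild-type replicates 1, 2 and 3, and 3, 14, 7, 10 and 8 without untreated replicates 1 to 5. With no filter 25 were lost, Retnla, Col8a1 and Mmp14 among them. The number of changed genes was 878 without treated wild-type replicate 1, 1275 without replicate 2, 953 without replicate 3 and 1188 without untreated replicate 2. It was 812 (553 up) with no filter, 3621 (1946 up) with median-of-ratios scaling, 3502 (1957 up) with quantile normalization, 3488 (1986 up) with both groups fitted alone, 5560 (3561 up) with array weights and 3705 after rescaling, where 2303 of them fell, so that most changes then went down. Rescaling moved the median of all genes from 0.04 to -0.18 (log2).

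**Figure D3:**
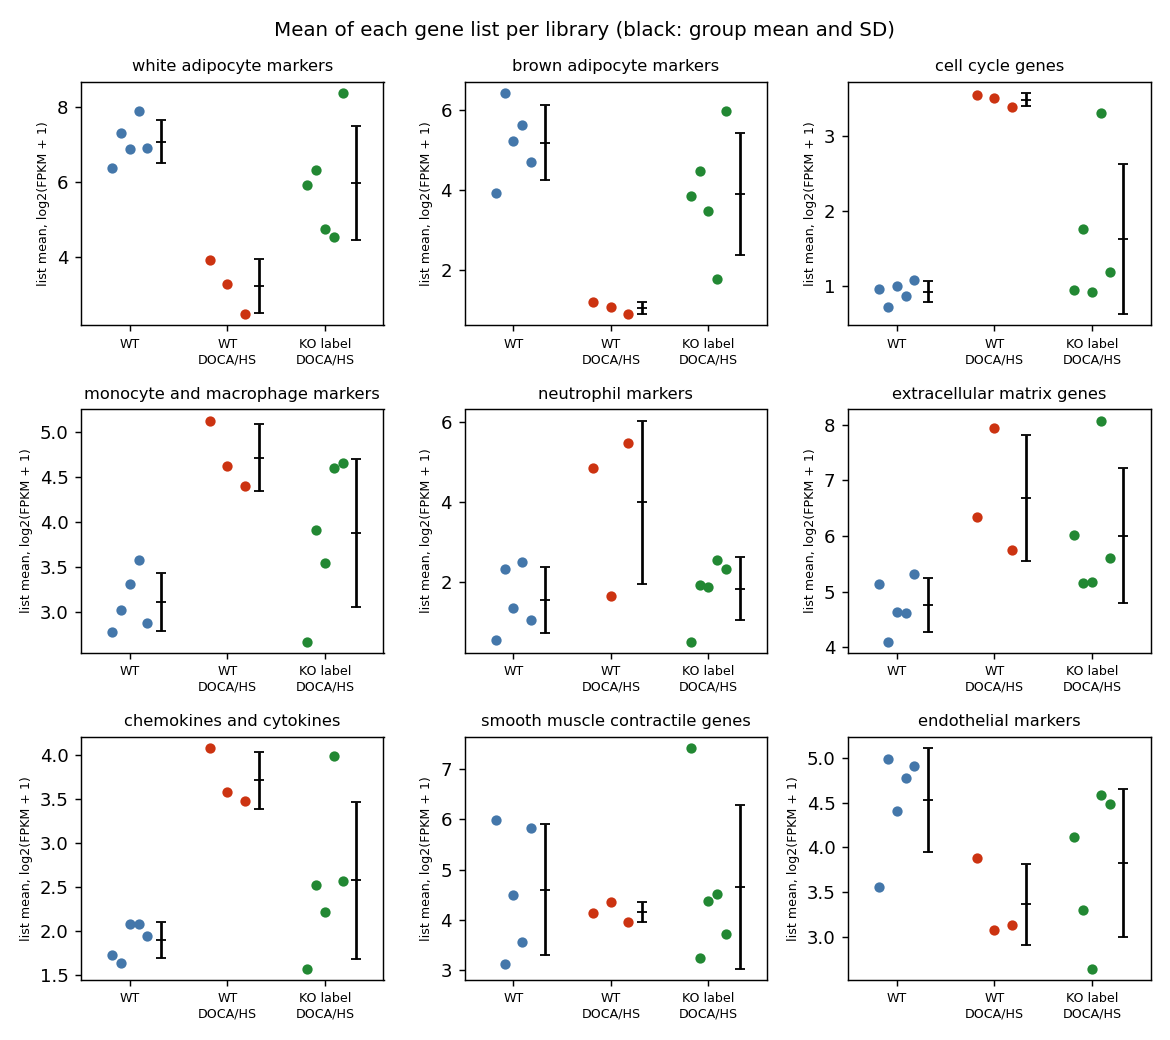
Each point is the mean log2(FPKM + 1) of a gene list in 1 library, and black bars show the group mean and SD. The white adipocyte list lies between 2.46 and 3.90 in treated wild type and between 6.36 and 7.90 in untreated wild type. The cell cycle list lies at 3.31 in labelled knockout replicate 4 and between 3.38 and 3.55 in treated wild type.

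The second comparison, labelled knockout against treated wild type, asks how treated aortas differed by genotype. Lists of fat cell and fibroblast genes were called higher in the libraries labelled knockout by camera, and lists of chemokine, neutrophil, macrophage and cell cycle genes lower. None of these calls held with an estimated correlation (adjusted p between 0.222 and 0.477), and in each of them fewer members passed over all genes than did not. Clec3b, a fibroblast marker, was 202 ± 199 FPKM (SD, n = 5) against 7.75 ± 5.51 FPKM (SD, n = 3), a rise of 4.42 (log2, SE 0.63). Arg1 was 3.80 ± 7.16 FPKM (SD, n = 5) against 101 ± 82.6 FPKM (SD, n = 3), and it fell by 5.00 (SE 0.72). In all, 160 of 14850 genes changed by limma, 55 upward and 105 downward, each by at least 2-fold. The libraries of both groups did not overlap in 1043 genes (7.02%), where chance gives 3.57%.

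The largest rises by the naming rule were in Ucp1 at 5.51 (log2, SE 0.98), Cidea at 5.33, Retnla at 5.19, Cox8b at 4.79, Clec3b, Gpd1 at 4.20, Pck1 at 3.90, Cytl1 at 3.76, Adig at 3.75 and Cfd at 3.68, with adjusted p between 0.0124 and 0.0472 in all but Cfd, which lay just under the threshold. Among brown adipocyte markers 4 of 10 rose, Dio2 by 2.92 among them (7 adjusted over the list alone; camera adjusted p = 4.89e-11, and adjusted p = 0.222 with an estimated correlation). Among white adipocyte markers 5 of 17 rose (17 adjusted over the list alone; camera adjusted p = 4.96e-19, and adjusted p = 0.222 with an estimated correlation). Among fibroblast markers 4 of 20 rose, namely Clec3b, Scara5 by 3.35, Pi16 by 3.35 and Entpd2 by 2.06 (8 up and 1 down adjusted over the list alone; camera adjusted p = 5.05e-07, and adjusted p = 0.293 with an estimated correlation). Ace, encoding angiotensin converting enzyme, rose by 2.03 as 1 of 8 renin-angiotensin genes (1 adjusted over the list alone; camera adjusted p = 0.00837, and adjusted p = 0.319 with an estimated correlation). That list call was lost under array weights and the filter at 5 FPKM. The Ace call was lost under the replicate term and, among others, without treated wild-type replicate 3. Dbp rose by 2.32 as 1 of 19 clock genes (4 adjusted over the list alone; camera adjusted p = 0.000426, and adjusted p = 0.445 with an estimated correlation).

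Spp1 fell by 5.58 (log2, SE 1.08), Cxcl2 by 5.01 and Il1b by 4.33. Among chemokines and cytokines 7 of 36 fell and 1 rose (14 and 2 adjusted over the list alone; camera adjusted p = 4.35e-06, and adjusted p = 0.402 with an estimated correlation). In the neutrophil list 4 of 9 fell (4 adjusted over the list alone; camera adjusted p = 2.47e-06, and adjusted p = 0.319 with an estimated correlation), namely Clec4d by 3.03, Il1r2 by 2.88, Csf3r by 2.72 and Trem1 by 1.98. Among macrophage markers Trem2 fell by 2.63 and the lectin gene Clec7a by 2.38, 2 of 22 members (9 down and 3 up adjusted over the list alone; camera adjusted p = 9.33e-05, and adjusted p = 0.477 with an estimated correlation). In the cell cycle list 7 of 20 fell (20 adjusted over the list alone; camera adjusted p = 5.26e-19, and adjusted p = 0.222 with an estimated correlation), including Ccnb2 by 2.45, Rrm2 by 2.26, Cdk1 by 2.20 and Plk1 by 2.11. The change was -4.42, -4.39 and -3.13 in the replication histone genes Hist1h2ap, Hist1h2ao and Hist1h2aj, -3.40 in Ube2c, -3.25 in Apoc2 and -3.20 in Bcl2a1b. Junb, the only changed member of 22 immediate early genes, is given above per library (1 adjusted over the list alone; camera adjusted p = 0.000108, and adjusted p = 0.477 with an estimated correlation).

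A further 5 lists were called without a changed member. Platelet and erythrocyte genes were lower (0 of 10, 10 adjusted over the list alone; camera adjusted p = 1.9e-09, and adjusted p = 0.222 with an estimated correlation), and treated wild-type replicates 1 and 3 held their high values. Oxidative phosphorylation genes were higher (0 of 22, 0 adjusted over the list alone; camera adjusted p = 1.98e-05, and adjusted p = 0.556 with an estimated correlation). Steroid responsive genes were higher (0 of 19, 5 adjusted over the list alone; camera adjusted p = 0.000209, and adjusted p = 0.402 with an estimated correlation). Endothelial markers were higher (0 of 19, 0 adjusted over the list alone; camera adjusted p = 0.00580, and adjusted p = 0.683 with an estimated correlation), as were smooth muscle genes (0 of 22, 0 adjusted over the list alone; camera adjusted p = 0.0309, and adjusted p = 0.736 with an estimated correlation). Without labelled knockout replicate 1 the mean difference of the smooth muscle list turned from 0.51 to -0.19 (log2), so this library carried its direction, and without replicate 2 it was 0.86. Without labelled knockout replicate 5 the mean difference went from 0.68 to 0.28 for oxidative phosphorylation genes, and that library was also the highest of its group for white (8.36) and brown (5.97) adipocyte markers. For endothelial markers it went from 0.46 to 0.72 without treated wild-type replicate 1 and to 0.76, 0.27 and 0.30 without labelled knockout replicates 3, 4 and 5. Among lists with changed members, it went from -2.15 to -3.32 and -1.42 for neutrophil markers without treated wild-type replicates 2 and 3, from 0.99 to 0.64 for fibroblast markers without treated wild-type replicate 3, from -0.84 to -0.54 for macrophage markers without labelled knockout replicate 1 and from 0.63 to 0.39 for renin-angiotensin genes without labelled knockout replicate 5. The endothelial call was lost without treated wild-type replicate 2 (adjusted p = 0.148) and under array weights and the replicate term. The smooth muscle call was lost without treated wild-type replicates 1 (adjusted p = 0.0981) and 2 (0.0632) and labelled knockout replicates 1 (0.784) and 3 (0.296), and under no filter, median-of-ratios scaling, quantile normalization and rescaling.

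The other 12 lists gave no call, with camera adjusted p between 0.0830 and 0.998. Among proteases and inhibitors Adam8 fell by 3.15 and Timp3 rose by 1.81 (7 down and 3 up of 27 adjusted over the list alone), and among matrix genes Spp1 fell and no other of 29 changed (1 down and 1 up adjusted over the list alone). In the selectin and leukocyte adhesion list none of 18 changed over all genes, with 3 lower and 1 higher adjusted over the list alone. No member changed, also adjusted over the list alone, among mast cell, kidney and adrenal, sex-linked, unfolded protein response, nerve, striated muscle, interferon responsive, B and plasma cell, and T and NK cell genes. The nerve and interferon lists had medians of 0.07 and 0.04 and means of -0.13 and -0.07, and the B and plasma list a median of -0.19 and an upward test.

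The count of 160 rested on single libraries, and none of the 40 gene calls named here held without treated wild-type replicate 3. Of these 40, 39 and 18 were lost without treated wild-type replicates 1 and 2, 35, 35, 37 and 36 without labelled knockout replicates 1, 2, 3 and 5, and 21, 21, 21 and 20 without untreated replicates 2 to 5. All 40 were lost with no filter and 37 with both groups fitted alone. With a pseudocount of 0.1, 11 were lost, namely Adam8, Apoc2, Bcl2a1b, Ccnb2, Cdk1, Cfd, Clec4d, Clec7a, Il1r2, Plk1 and Trem2. With a pseudocount of 0.5 Clec4d and Plk1 were lost, with the filter at 5 FPKM Cdk1 and Plk1, with no trend Cfd, Clec4d, Cytl1, Plin1 and Plk1, and with the replicate term Ace, Cfd, Plin1 and Timp3. It was 0 without treated wild-type replicate 3 and 4 without replicate 1, and it was 1286 (311 up) without labelled knockout replicate 4 and 19, 17, 13 and 12 without labelled knockout replicates 1, 2, 3 and 5. Without untreated replicates 2, 3, 4 and 5, which enter through the shared spread, it was 45, 46, 46 and 46. It was 0 with no filter, 4 (1 up) with both groups fitted alone, 511 (184 up) with median-of-ratios scaling, 478 (164 up) with quantile normalization 1169 (382 up) with array weights and 278 (57 up) with a term for replicate number. After rescaling it was 457, of which 290 rose, and the median of all genes moved from -0.08 to 0.11 (log2). The direction of the majority also turned with a pseudocount of 0.1 (107 of 140 up) and a filter at 5 FPKM (83 of 148 up).

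The third comparison, labelled knockout against untreated wild type, asks how far treated aortas labelled knockout lay from untreated ones. No gene changed by limma, and the smallest adjusted p was 0.914. At an unadjusted p under 0.05 there were 788 genes, where 742.5 are expected by chance. That number was 1574 with median-of-ratios scaling, 1620 with quantile normalization and 1652 after rescaling. It was 1536 without labelled knockout replicate 5, with a smallest adjusted p of 0.0666, and 431 without untreated replicate 2. The libraries of both groups did not overlap in 125 genes (0.842%), where chance gives 0.794%. Comp, a matrix gene of the vessel wall and cartilage, was 69.3 ± 50.1 FPKM (SD, n = 5) against 10.9 ± 6.07 FPKM (SD, n = 5), a difference of 2.35 (log2, SE 0.52). Ccl8, a monocyte attractant, was 44.3 ± 31.9 FPKM (SD, n = 5) against 6.36 ± 4.41 FPKM (SD, n = 5), and Aqp1 was 80.7 ± 58.2 FPKM (SD, n = 5) against 214 ± 80.3 FPKM (SD, n = 5), each with an adjusted p of 0.914.

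Camera called 14 lists in this comparison, and none of their members changed over all genes. Extracellular matrix genes were higher by a median of 1.22 (camera adjusted p = 2.82e-16), monocyte and macrophage markers by 0.97 (1.4e-10), cell cycle genes by 0.72 (1.97e-10), chemokines and cytokines by 0.72 (1.58e-08), striated muscle genes by 1.27 (2.87e-08), proteases and inhibitors by 0.52 (2.96e-05), fibroblast markers by 0.41 (0.000146) and immediate early genes by 0.35 (0.00224). With an estimated correlation these gave adjusted p = 0.381 for 6 of them, adjusted p = 0.397 for proteases and adjusted p = 0.641 for immediate early genes with an estimated correlation. Oxidative phosphorylation genes were lower, with a median of -0.86 (camera adjusted p = 3.31e-10), as were white adipocyte markers at -1.05 (8.32e-09), endothelial markers at -0.67 (4.28e-07), brown adipocyte markers at -1.30 (6.64e-07), nerve markers at -0.86 (4.86e-05) and steroid responsive genes at -0.32 (0.0433). They gave adjusted p = 0.381 with an estimated correlation, except adjusted p = 0.659 for steroid responsive genes. The immediate early call was lost without labelled knockout replicate 4 (adjusted p = 0.136). The steroid call was lost without untreated replicates 2 (adjusted p = 0.131), 4 (0.248) and 5 (0.0684) and labelled knockout replicates 2 (0.0776), 3 (0.0867) and 4 (0.310), and under a pseudocount of 0.1, median-of-ratios scaling, quantile normalization and rescaling. The fibroblast call was lost under array weights. Without labelled knockout replicate 4 the mean difference went from 1.25 to 0.73 (log2) for matrix genes, from 0.70 to 0.28 for cell cycle genes, from 0.68 to 0.33 for chemokines and cytokines, from 1.43 to 0.60 for striated muscle genes, from 0.49 to 0.19 for proteases, from 0.45 to 0.0559 for immediate early genes and from -1.27 to -0.74 for brown adipocyte markers. Without labelled knockout replicate 5 it went from 0.51 to 0.33 for fibroblast markers, from -1.10 to -1.70 for white adipocyte markers, from -0.77 to -1.18 for oxidative phosphorylation genes and from -0.42 to -0.68 for steroid responsive genes. Without labelled knockout replicate 3 it went to -0.16 for steroid responsive genes, to 0.75 for immediate early genes and from -0.70 to -0.41 for endothelial markers, and without replicate 2 to 0.68 for immediate early genes. Without untreated replicate 1 it was -0.26 for nerve markers, and -0.999 with it. Adjusted over the list alone, Comp passed among 29 matrix genes and Kdr and Aqp1 among 19 endothelial markers, and no member of the other 25 lists passed.

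The other 13 lists gave camera adjusted p between 0.366 and 0.941. In the selectin, mast cell, T and NK cell and renin-angiotensin lists median and mean had opposite signs, each within 0.2 of 0. Labelled knockout replicate 4 held the highest value of its group for many of the genes named, with Col1a1 at 3130 FPKM against 107 to 208 FPKM in the other 4 and Spp1 at 218 FPKM against 1.29 to 4.78 FPKM. The count of changed genes was 0 without it, and 0 under every alternative run.

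The last comparison asks whether the genes changed by treatment in wild type took the opposite direction between the libraries labelled knockout and treated wild type. All 160 genes changed in the second comparison had changed in the first in the other direction, 105 up and then down and 55 down and then up. Counts of 8.57 and 2.93 would be expected if the calls were independent. The same 3 treated wild-type libraries enter both comparisons with opposite signs, so opposite changes arise without any effect. In 100 simulated draws of unchanged groups that share libraries in this way, the mean count was 0.68 and the highest 65, with any such gene in 4 draws. Across genes, which are not independent replicates, the correlation of both fold changes was -0.91, against -0.61 in the simulations, and the covariance was -0.675 against a mean of -0.127 and a lowest value of -0.341. Signs were opposite in 85.5% of genes, against 71.1% in the simulations. The draws hold no effect in either comparison, whereas 2003 genes changed in the first comparison of the data. The second fold change equals the third minus the first, and the third comparison gave 0 changed genes. A gene called in the second was thus nearly bound to oppose the first. Neither the draws nor the counts for independent calls allow for this, so they do not measure a reversal. Treated wild type has 3 libraries and cannot be divided between both comparisons.

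The count of opposite changes was 0 without treated wild-type replicate 3, 4 without replicate 1, 1186 without labelled knockout replicate 4, and 19, 17, 13 and 12 without labelled knockout replicates 1, 2, 3 and 5. It was 45, 46, 45 and 46 without untreated replicates 2, 3, 4 and 5.

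**Figure D4:**
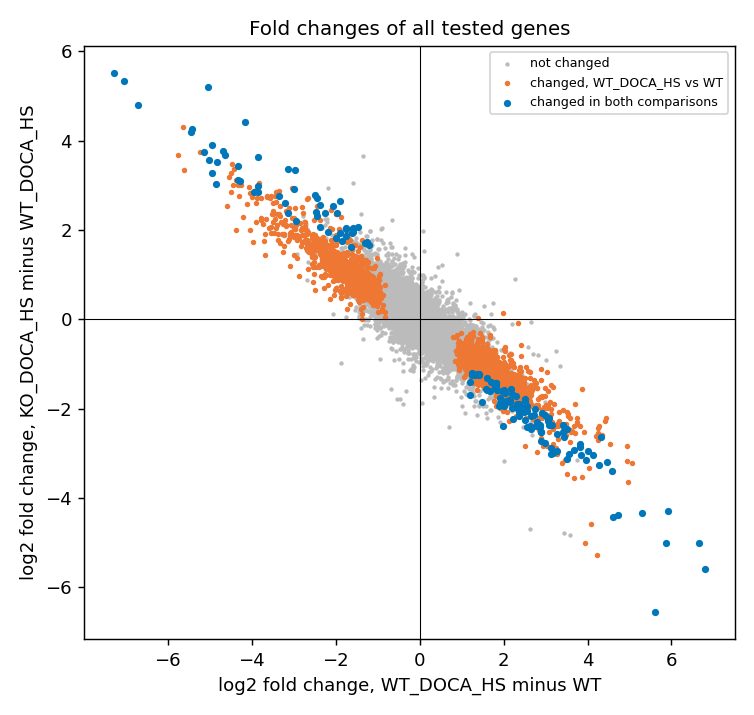
Each point is 1 of 14850 genes, with its log2 fold change in treated against untreated wild type on the horizontal axis and in labelled knockout against treated wild type on the vertical axis. The 160 genes changed in both comparisons lie in the upper left (55) and lower right (105), and both axes share the 3 treated wild-type libraries.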

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

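The tests that weigh the explanations for the 3 patterns below were chosen only after the result was seen, and the tests of other splits of the libraries were planned.

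In each group of 5 libraries, the highest or lowest value was picked out when its gap to the nearest other value took more than the part of the range that Dixon's 95% limit allows. This was the case in 36 of 346 tests, where chance gives about 17.3, so about 1 in 20 groups would be picked out without any cause. Groups of 3 libraries were not tested.

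Labelled knockout replicate 4 accounted for 12 of these results. It lay at 70.4 on the first principal component, with the other 4 libraries labelled knockout between -35.3 and -18.3. In log2(FPKM + 1) it held 7.78 for Spp1, 5.81 for Cxcl2, 9.03 for Hmox1, 4.14 for Arg1, 8.38 for Thbs1, 11.61 for Col1a1, 8.01 for Col8a1, 8.81 for Mmp14, 5.25 for Ube2c and 0.83 for Trem1, each above the other 4, and 0.95 for Inmt, below them.

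Untreated replicate 1 stood apart at 75.1 on the second principal component, with 5.87 for the mean of the nerve and Schwann cell list and 1.88 for the striated muscle list. In log2(FPKM + 1) it held the highest values of its group for Th (9.59), Prph (9.31), Atp1b1 (7.65), Agtr1a (5.67), Acta1 (3.26), Tnnt3 (3.17) and Tnni2 (2.37), and the lowest for Inmt (5.40) and Timp3 (6.65). Untreated replicate 3 held 4.03 for the B and plasma cell list, 5.20 for Cd79a and the lowest circadian clock list mean, 2.44. Untreated replicate 5 had 6.63% of its FPKM sum in ribosomal-RNA-like genes, with 0.871% to 2.44% in the other untreated libraries. Untreated replicate 4 was lowest for Bhlhe40 (1.81) and untreated replicate 2 for Oas1a (1.17).

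Labelled knockout replicate 3 had 10219 genes at 1 FPKM or more, with 12884 to 13744 in the other libraries labelled knockout. Labelled knockout replicate 5 was highest for the oxidative phosphorylation list (8.39) and for Ndufa1 (9.12). Labelled knockout replicate 2 was the only library of its group with Junb above 0 (3.90). Labelled knockout replicate 1 was lowest for S100a9 (0.23) and Ccl8 (1.12).

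The first pattern weighed is the fall of adipocyte markers in treated wild type. Scaling to a total held by mitochondrial, haemoglobin, ribosomal-RNA-like and the other genes left out in rescaling was argued against. The white adipocyte list had a median log2 change of -4.30 after rescaling and -4.00 as deposited, with 17 of 17 members changed both times. A lower share of fat in the pieces taken, with no other change, would raise what is not fat alike. The pair of lists tested first, macrophage and smooth muscle, moved apart by 2.06 (log2, pooled SD 1.27) and missed the threshold (exact permutation p = 0.0714). Macrophage genes moved away from endothelial genes by 2.77 (pooled SD 0.466) and fibroblast genes by 2.09 (pooled SD 0.429), each with an exact permutation p of 0.0179. From nerve and Schwann cell genes they moved by 2.48 (pooled SD 1.64, exact permutation p = 0.0893). These further pairs were outside the prediction, and such cells may lie in the fat itself, so they do not decide. The cell cycle and smooth muscle pair, added once the first had been seen, moved apart by 3.01 (pooled SD 0.973, exact permutation p = 0.0357). By the prediction this would argue against a lower share of fat alone. The pair was chosen when the changes of both lists were already known, however. Only 2 of 20 cell cycle genes were detected in every untreated library, so this pair does not decide either. A lower share of fat beside other changes cannot be told apart from an effect of the treatment on fat cells, since the smooth muscle list, which it would raise, changed by -0.45 (pooled SD 1.07, exact permutation p = 0.589).

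The second pattern is the place of labelled knockout replicate 4 beside treated wild type. For a swap with a treated wild-type library, 0 of the 3 treated wild-type libraries lay nearer to the other libraries labelled knockout on the first principal component. This argues against a swap only if a true knockout must lie with those other libraries. The places were known before the test was chosen, so it does not decide the question. A wrong label on this library alone cannot be told apart from a strong response to treatment in this sample. Its log2 Selplg level relative to leukocyte genes was -3.33, against -3.17 in treated wild-type replicate 2, whose own label was not tested. A response that varies between treated mice may give the same place.

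The third pattern is Selplg RNA in the libraries labelled knockout. Relative to the leukocyte genes Ptprc, Itgb2, Laptm5, Cd53 and Coro1a, which were chosen after the data were seen, 3 of the 5 libraries labelled knockout lay in the untreated range of -1.29 to -0.31 (log2). The others lay at -3.14 and -3.33. Wrong labels on single libraries cannot be told apart from a knockout allele that still gives RNA, since treated wild-type replicate 2 also lay at -3.17 and a value per gene does not show which part of the RNA was read. This takes the label of treated wild-type replicate 2 as right, which was not tested. Treated wild-type replicates 1 and 3 lay at -1.19 and -0.04. Over tested genes, replicate 2 correlated at 0.944 with labelled knockout replicate 4, and at 0.907 and 0.895 with treated wild-type replicates 1 and 3.

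Splits of the libraries into groups of the same sizes tested whether chance can be excluded. For treated against untreated wild type, 1 of 56 splits, the real one, gave as many as 2003 genes, and the highest other gave 5, which argues against chance. That is the smallest share that 56 splits allow, so chance is not excluded. Mixed splits also put the difference between the groups into the spread, which can lower their counts. For labelled knockout against treated wild type, 6 of 56 splits gave at least 160 genes, so chance cannot be excluded. The highest other gave 1304, for treated wild-type replicate 3 with labelled knockout replicates 2 and 3 against the rest, and the cause of that count was not tested. For labelled knockout against untreated wild type the real count was 0, so 100 of 100 drawn splits had to give at least as many, and the test says nothing about chance. The highest other gave 183.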

How the results depend on the processing

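The rescaling and, for opposite changes, the replicate term, array weights, no trend, the 2-fold minimum and libraries left out were tests chosen only after the result was seen. The cause of the shifts below was not tested, except that fewer libraries or groups leave fewer degrees of freedom.

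With no filter on low values, genes changed were 812 (treated against untreated wild type) and 0 (labelled knockout against treated wild type), with 0 opposite changes. With median-of-ratios scaling they were 3621 and 511, with 496 opposite changes, and with quantile normalization 3502 and 478, with 465. With the 2 compared groups alone they were 3488 and 4, with 4 opposite changes, and with array weights 5560 and 1169, with 1157. With the replicate block the second count was 278, with 275 opposite changes. With rescaling without mitochondrial, haemoglobin and rRNA-like genes and unnamed models of very high level they were 3705 and 457, with 435 opposite changes. Of these genes 1922 and 153 were shared with the deposited values. Pseudocounts of 0.1 and 0.5, the filter at 5 FPKM, no trend and the 2-fold minimum kept these counts within 1.5 times, but not all of the genes. Of the 160 genes of the second comparison, 87 were shared with a pseudocount of 0.1 (107 up and 33 down), 137 with 0.5, 100 with the filter at 5 FPKM and 121 with no trend. Labelled knockout against untreated wild type gave 0 genes under every alternative run.

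With an estimated correlation 0 of 18, 0 of 15 and 0 of 14 list calls held in the 3 comparisons, and with fry 8, 0 and 0 lists were called. Of the 18 calls of the first comparison, 11 were lost with fry, and the kidney and adrenal cortex list, which camera did not call, was added. The calls kept were macrophage, chemokine, neutrophil, platelet and erythrocyte, cell cycle and both adipocyte lists (fry adjusted p from 0.00633 to 0.0278). Under the other settings, the number of lists called stayed within 1.5 times, though calls of single lists were lost, as named with each comparison.

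Leaving out 1 library gave 878 to 2449 changed genes in the first comparison, 0 to 1286 in the second and 0 to 1186 opposite changes. The Selplg difference ranged from 0.90 to 2.61, from -2.97 to -1.26 and from -0.75 to -0.0935 in the 3 comparisons, with exact p from 0.0476 to 0.333, 0.0476 to 0.286 and 0.0476 to 0.865.

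Signs turned in 100 cases, 67 with a library left out and 33 under other settings, and 3 of the 100 were called. The values that follow are adjusted p of lists unless a gene is named. For treated against untreated wild type, the T and NK cell list gave 0.939 with fry, 0.995 with a pseudocount of 0.1 and 0.894 with rescaling, and the B and plasma cell list 0.951 with a pseudocount of 0.1 and 0.894 with rescaling. Jchain changed by -0.44 (log2) with the replicate block and by -0.13 with rescaling.

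For labelled knockout against treated wild type, the B and plasma cell list gave 0.923 with fry, 0.930 with a pseudocount of 0.1, 0.650 with no filter on low values, 0.760 with the 2 compared groups alone, 0.859 with array weights and 0.876 with rescaling. The interferon list gave 0.923 with fry, 0.625 with no filter and 0.736 with array weights, the nerve list 0.692 with no filter and 0.874 with array weights, and the T and NK cell list 0.916 with median-of-ratios scaling and 0.997 with the replicate block.

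For labelled knockout against untreated wild type, the platelet and erythrocyte list gave 0.981 and 0.996 with pseudocounts of 0.1 and 0.5, 0.916 with median-of-ratios scaling, 0.995 with the replicate block and 0.801 with rescaling. The mast cell list gave 0.818 with no filter and 0.687 with the filter at 5 FPKM, which gave 0.339 for the renin-angiotensin list. With array weights the selectin list gave 0.691, the neutrophil list 0.565 and S100a9 changed by -0.49. With rescaling the T and NK cell and the B and plasma cell lists gave 0.958 each.

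With each library left out, log2 changes ranged as follows. For labelled knockout against untreated wild type, Cd79a ranged from -0.93 to 0.15 and S100a9 from -0.0164 to 1.46. For treated against untreated wild type, Cd79a ranged from -0.88 to 0.32 and Jchain from -0.31 to 0.68. For labelled knockout against treated wild type, Ddx3y ranged from -0.0882 to 0.33, Prph from -3.05 to 0.26, Tnni2 from -2.03 to 0.25 and Tnnt3 from -2.14 to 0.14.

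With each library left out, adjusted p of lists in labelled knockout against untreated wild type ranged from 0.0474 to 0.890 for B and plasma cells (0.0474 and called without untreated replicate 3), 0.0345 to 0.880 for the circadian clock, 0.0867 to 0.978 for interferon, 0.241 to 0.956 for mast cells, 0.0179 to 0.911 for neutrophils, 0.192 to 0.926 for platelets and erythrocytes, 0.572 to 0.995 for renin-angiotensin, 0.129 to 0.759 for selectins, 0.598 to 0.982 for sex-linked genes, 0.000726 to 0.772 for smooth muscle (0.000726 and called without labelled knockout replicate 1), 0.197 to 0.978 for T and NK cells and 0.212 to 0.978 for the unfolded protein response. In labelled knockout against treated wild type they ranged from 0.464 to 0.961 for B and plasma cells, 0.00805 to 0.797 for matrix, 0.187 to 0.956 for interferon, 0.0258 to 0.826 for mast cells, 0.00737 to 0.932 for striated muscle (0.00809 and called without treated wild-type replicate 3) and 0.423 to 0.984 for T and NK cells. In treated against untreated wild type they ranged from 0.176 to 0.910 for B and plasma cells and 0.454 to 0.987 for T and NK cells.

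The replicate numbers gave no clear pairing of the libraries. Of 13 libraries, 4 were best matched by one with their own number, and residual correlations of libraries with the same number lay between -0.29 and 0.28. Their mean was 0.115 between untreated and treated wild type, against -0.0305 for other numbers. It was 0.0600 against -0.0120 between untreated wild type and labelled knockout, and -0.0414 against 0.0124 between treated wild type and labelled knockout. A pairing cannot be excluded. Depth behind the values is unknown, so it cannot be said which low values it limits.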

Other observations

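The values below are given per library, apart from the comparisons, and were picked out only after the result was seen. Th, Kap, Ckm and Ddx3y are members of the planned lists.

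Th, a gene of catecholamine synthesis, stood at 768 FPKM in untreated replicate 1, at 40.4 FPKM in treated wild-type replicate 1 and at 1.01 FPKM or less in the other 11 libraries. Kap, a kidney gene, stood at 279 FPKM in untreated replicate 3 and 20.3 FPKM in untreated replicate 5. Alb, a liver gene, stood at 74.1 FPKM in labelled knockout replicate 1. Ckm, a gene of striated muscle, stood at 38.5 FPKM in treated wild-type replicate 3 and 56.2 FPKM in labelled knockout replicate 4. The Y-linked gene Ddx3y was present in all 13 libraries.

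Cygb was the only tested gene in which all 5 libraries labelled knockout (74.6 to 108 FPKM) were separated from all 8 wild-type libraries (25.3 to 66.8 FPKM). Chance gives about 23.1 such genes among 14850.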
